A study of Mus musculus with 3 samples.

How the data were processed

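Cells of mouse brain, sorted by flow cytometry as CD45int CD11b+, were profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends with unique molecular identifiers (UMIs). The 3 deposited matrices, 1 per group and each from a pool of 4 mice, hold whole-number UMI counts per gene and barcode, per the file headers and the values themselves, with no normalization. Per the submitters' processing notes, Cell Ranger 5.0.1 and Seurat 4.3.0 were used with the mm10 build, while per the file headers the matrices came from cellranger 7.0.1. Which version made the deposited counts, whether intronic reads were counted and whether counting used strand are not given in the sources used here. Intronic counting would add UMIs to long genes and to nuclear RNA. Barcodes had been filtered for cells before deposit, with a lowest total of 500 UMIs in each library. Libraries were grouped by the treatment named in the labels, sham + PBS, NMOSD + control peptide and NMOSD + APOE130-149.

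Gene coordinates came from a GRCm38 annotation, the same assembly as mm10, and were found for 32158 of 32285 gene identifiers. Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, which left out 9.48% of sham, 5.56% of control peptide and 6.90% of APOE130-149 barcodes, and 11267 of 12155 cells remained. Counts of all 3 libraries were scaled to 10000 per cell and log-transformed, and 2000 variable genes and 30 principal components were used for a graph of 15 neighbours, clustered with Leiden at resolution 1 (seed 1) without integration of libraries. Scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15 were used, with matplotlib 3.10.9 for figures. Of 20 clusters, 9 were called microglia-like and 5 stayed unnamed. A cluster took the name of a cell type only from marker lists of 17 cell types, when at least 3 markers were detected in at least 25% of its cells and, for types other than microglia, at least 2, and more than of any other type, were among its top 10 genes by fold. Microglia-like clusters also needed microglia markers at levels not far below those in the other cells. A cluster with a median UMI count more than 3 times below that of its own library and no microglia marker among its top 10 genes was not called microglia-like and, with no other name, was left unnamed. These naming thresholds were set after the data were seen.

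Doublets were kept. Scrublet's own threshold called 8 of 11267 cells (0.0710%), which was taken as a failure of the caller, so removal of the 6% of cells with the highest score and removal of cells above 2 times the library median of UMIs were tried instead.

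With 1 library per group no test across samples was possible, and no p-value, standard error or count of changed genes was computed. UMIs of microglia-like cells were summed per library and given as CPM, counts scaled to those sums, with exact 95% Poisson intervals and exact conditional (Clopper-Pearson) intervals for ratios. Shares of cells carry exact Clopper-Pearson binomial intervals. A count of 0 was given an upper limit of 3 counts. Microglia-like sums of 28083268 UMIs in sham, 46997343 with the control peptide and 24589042 with APOE130-149 put that limit at 0.107, 0.0638 and 0.122 CPM. Intervals of list medians came from 400 Poisson draws.

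The comparisons, the marker lists, a sex-linked check list, 22 gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. In both main comparisons the rule named, among genes with at least 50 CPM and 50 UMIs in the higher library and a ratio interval excluding 1, the 12 with the highest and the 12 with the lowest ratio. Mitochondrially encoded, ribosomal protein, haemoglobin and unnamed predicted genes were excepted. It also named list members with the highest and lowest ratios at 10 CPM or more, Apoe and the sex-linked genes. The example genes given for lists beyond those extremes, the markers of other cell types and the genes of the closing section were chosen after their values were seen. Each list was described by its members with at least 10 CPM in either library, those at least 1.5-fold higher or lower, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of like expression. The lists were homeostatic microglia, disease-associated microglia, type I interferon response, MHC class I, MHC class II, inflammatory cytokines and NF-kB, chemokines, complement, Fc gamma receptors and signalling, lysosome and phagocytosis, cholesterol efflux and LXR targets, cholesterol synthesis, apolipoprotein E receptors, proliferation, immediate early and heat shock, glycolysis, nuclear genes of oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, alternative activation and resolution, oxidative stress response, and TGF-beta signalling. Lists share members. Among these, Jun is in the homeostatic and immediate early lists, Mertk in the homeostatic and lysosome lists, Axl, Cd68, Ctsb, Ctsd and Ctsz in the disease-associated and lysosome lists, Trem2 in the disease-associated and apolipoprotein E receptor lists, and Hmox1 in the alternative activation and oxidative stress lists. Splicing factors with retained introns and nuclear-retained long RNAs were added as lists after the data were seen. Clec7a, Mx1 and Mx2 were not analysed here.

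The relation of both main comparisons was computed over genes with at least 10 CPM in any library, beside 100 simulated sets of libraries without differences and beside a random division of the control peptide library's UMIs. Cells were thinned to 2000 UMIs for shares of cells with a UMI. Alternatives covered the filter on cells (none, or at least 1000 genes and at most 5% mitochondrial UMIs), Leiden resolutions 0.5 and 2, all cells in place of microglia-like cells, median-of-ratios and TMM factors, a total without mitochondrially encoded and ribosomal protein genes, equal weight per cell, thinning to 2000 or 1000 UMIs, removal of Scrublet calls, and filters on low genes. Added after seeing the data were the 2 doublet settings, inclusion of unnamed low-UMI clusters of at least 400 cells, class shares over cells of named clusters only, the relation without the immediate early list, and, for each gene, leaving out the 0.25% of cells with most of its UMIs. The count of immediate early genes higher in both comparisons was also added then.

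The steps were tested on simulated data with the real means and library sizes of NMOSD + control peptide against sham. Ratio intervals held the known fold for 100% of 34 genes at 0.25-fold, 94.1% of 34 at 0.5-fold, 93.9% of 33 at 1.5-fold, 93.9% of 33 at 2-fold and 100% of 33 at 4-fold, and held 1 for 95.0% of 8083 unchanged genes. Of random lists of 20 genes, 5% were said to stand apart, a share that the bound at the middle 95% of random lists sets in advance. The simulated counts were Poisson draws of summed UMIs, without cells. These checks therefore do not cover UMIs held by few cells or lists whose genes vary together.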

Results

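Single-cell RNA sequencing was carried out on brain cells of Apoe knockout mice, sorted as CD45int CD11b+, a gate that takes in microglia, the resident macrophages of the brain. Cells were taken at day 4 after sham treatment or after induction of NMOSD, the usual abbreviation of neuromyelitis optica spectrum disorder, an autoimmune disease of the central nervous system. There were 3 groups: sham + PBS, NMOSD + control peptide, and NMOSD + APOE130-149, a peptide named after apolipoprotein E. Each group was 1 library, made from a pool of 4 mice, so no difference between groups has a replicate check and none was tested. The sham library held 4674 barcodes and 32712199 unique molecular identifiers (UMIs), the control peptide library 5306 barcodes and 61469677 UMIs, and the APOE130-149 library 2175 barcodes and 32060750 UMIs. After the filter on cells, 4231, 5011 and 2025 cells remained, in the same order, with medians of 7124, 7848 and 9991 UMIs per cell. Intervals in brackets are 95% intervals that cover counting error only, exact Poisson for levels, exact conditional for ratios and exact binomial for shares. Spread between mice or between library preparations is not in them.

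The knocked-out gene itself (Apoe, ENSMUSG00000002985, GRCm38 chromosome 7, 19696109 to 19699188) gave UMIs in every library. In microglia-like cells its level was 78.6 CPM (UMIs of the gene scaled to all UMIs of these cells) [75.4 to 82.0] in sham, 107 [104 to 110] with the control peptide and 123 [119 to 127] with APOE130-149. The knockout allele and its deleted part are not named in the sources used here, and a tag at the 3′ end of a transcript from outside the deleted part checks nothing, so these levels do not test the genotype. Xist, the RNA of the inactive X chromosome, stood at 2347, 2311 and 2155 CPM in sham, control peptide and APOE130-149 microglia-like cells. Of the Y-linked genes, Ddx3y and Eif2s3y had 0 UMIs in each library's microglia-like cells, which allows up to 0.107, 0.0638 and 0.122 CPM at 3 counts. Kdm5d had 1 UMI in sham, and Uty had 3 UMIs in sham and 1 with APOE130-149.

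The sorted cells were mostly microglia-like in each library, and border-associated macrophage-like cells made up larger shares of both NMOSD libraries than of sham. Microglia-like cells were 67.8% [66.4 to 69.2] of cells in sham, 81.4% [80.3 to 82.5] with the control peptide and 77.5% [75.6 to 79.3] with APOE130-149. Border-associated macrophage-like cells, led by genes of macrophages of the meninges and vessels, were 1.65% [1.29 to 2.09], 4.55% [3.99 to 5.16] and 4.69% [3.81 to 5.70]. Neutrophil-like cells were 1.35% [1.02 to 1.74], 2.55% [2.14 to 3.03] and 3.65% [2.88 to 4.57], and monocyte or monocyte-derived macrophage-like cells 0.827% [0.577 to 1.15], 1.20% [0.915 to 1.54] and 1.88% [1.33 to 2.57], with overlapping intervals of sham and the control peptide. Sham's total holds more unnamed cells than the others. Over cells of named clusters only, border-associated macrophage-like cells were 2.28% [1.78 to 2.87], 4.94% [4.33 to 5.60] and 5.17% [4.20 to 6.28], neutrophil-like cells 1.86% [1.41 to 2.40], 2.77% [2.32 to 3.29] and 4.03% [3.17 to 5.03], and monocyte-like cells 1.14% [0.796 to 1.58], 1.30% [0.992 to 1.67] and 2.07% [1.47 to 2.83], where for neutrophil-like cells too the intervals of sham and the control peptide overlap. These shares moved with the clustering and the filters. Border-associated macrophage-like cells were 0.733%, 2.35% and 2.57% at Leiden resolution 2 and no cluster took that name at resolution 0.5, and neutrophil-like cells were 2.94%, 3.33% and 4.20% without the cells of highest doublet score. Cells of these 3 classes also carried RNA of microglia, and more of it in the NMOSD libraries: P2ry12 stood at 1429, 1942 and 2021 CPM in border-associated macrophage-like cells, at 463, 1534 and 1939 CPM in neutrophil-like cells and at 50.02, 213 and 247 CPM in monocyte-like cells, against 2627, 2422 and 2621 CPM in microglia-like cells. Border-associated macrophage-like cells had medians of 13699, 23634 and 19372 UMIs, against 8347, 7977 and 10499 in microglia-like cells. Doublets were kept. T cell-like cells numbered 1 in sham, 35 with the control peptide and 17 with APOE130-149, with P2ry12 at 1266, 1076 and 703 CPM. Endothelial cell-like cells numbered 2, 10 and 21, with P2ry12 at 63.7, 2111 and 1479 CPM. In the NMOSD libraries both classes thus carried RNA of microglia too, which limits what these counts show. Cells in the ependymal or choroid plexus cell-like class numbered 35, 81 and 23. In sham that last class carried 10447 CPM of Ttr, a choroid plexus gene, against 195390 and 170006 CPM in the NMOSD libraries, so its sham cells are not comparable with the others. The CD45int CD11b+ gate sets these shares in part. Clusters left without a name, by thresholds set after the data were seen, held 27.5% [26.1 to 28.8] of sham cells, 7.80% [7.07 to 8.58] with the control peptide and 9.23% [8.01 to 10.6] with APOE130-149. The largest of them, with a median of 1197 UMIs per sham cell, was 23.6% of sham and 2.63% and 1.43% of the NMOSD libraries. The microglia-like share is therefore not ordered between groups: with at least 1000 genes and at most 5% mitochondrial UMIs per cell it was 86.4%, 83.1% and 79.7%, and over named clusters only 93.5%, 88.3% and 85.4%, with sham highest in both.

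**Figure D1:**
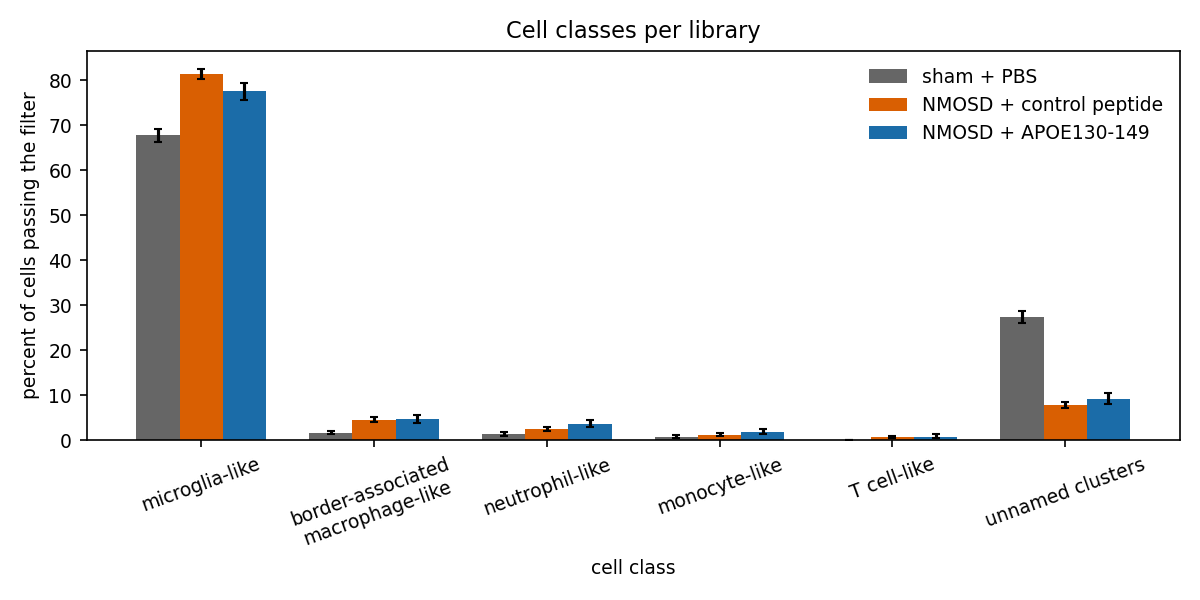
Cell classes per library: bars give the percent of cells passing the filter (vertical axis) in 6 classes (horizontal axis) for the 3 libraries, with exact 95% binomial intervals; the endothelial cell-like and choroid plexus cell-like classes are not drawn. Microglia-like cells are the tallest bars, 67.8% in sham, 81.4% with the control peptide and 77.5% with APOE130-149, and unnamed clusters hold 27.5% of sham cells.

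Within the microglia-like class the libraries also held different clusters. Clusters 0 and 3 held 79.2% of the sham microglia-like cells, 10.3% of those with the control peptide and 5.03% of those with APOE130-149. Clusters 1, 2, 5 and 8 held 5.61%, 70.3% and 74.5%, and clusters 6, 7 and 12 held 15.2%, 19.4% and 20.4%. Every level below was summed over all of these clusters, from 2869, 4078 and 1570 cells with 28083268, 46997343 and 24589042 UMIs.

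The first comparison, NMOSD + control peptide against sham + PBS, asks how microglia of Apoe knockout mice differ after NMOSD induction with the control peptide. These groups differ both in induction and in control peptide against PBS, which the design cannot tell apart. Immediate early genes, switched on within minutes of a stimulus and many of them coding for transcription factors, were higher in the NMOSD library. Of 25 measured members of the immediate early and heat shock list, 17 were at least 1.5-fold higher, 0 were at least 1.5-fold lower and 8 were neither, with a median log2 ratio of 1.45 (percentile 100 among random lists matched on level). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a zinc finger transcription factor, stood at 9.51 CPM in sham and 110 CPM in the NMOSD library, 11.6-fold higher [10.3 to 13.2]. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), a subunit of AP-1, was 5.94-fold higher [5.69 to 6.20], at 83.8 against 498 CPM, and Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) was 6.10-fold higher [5.86 to 6.36], at 92.8 against 566 CPM. The 8 that were neither were all genes of heat shock proteins and other chaperones. Of these, Hspa1a stood at 8.15 CPM in sham and 11.6 CPM in the NMOSD library and Hspa1b at 14.99 and 10.8 CPM, a near-identical pair that can share reads.

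**Figure D2:**
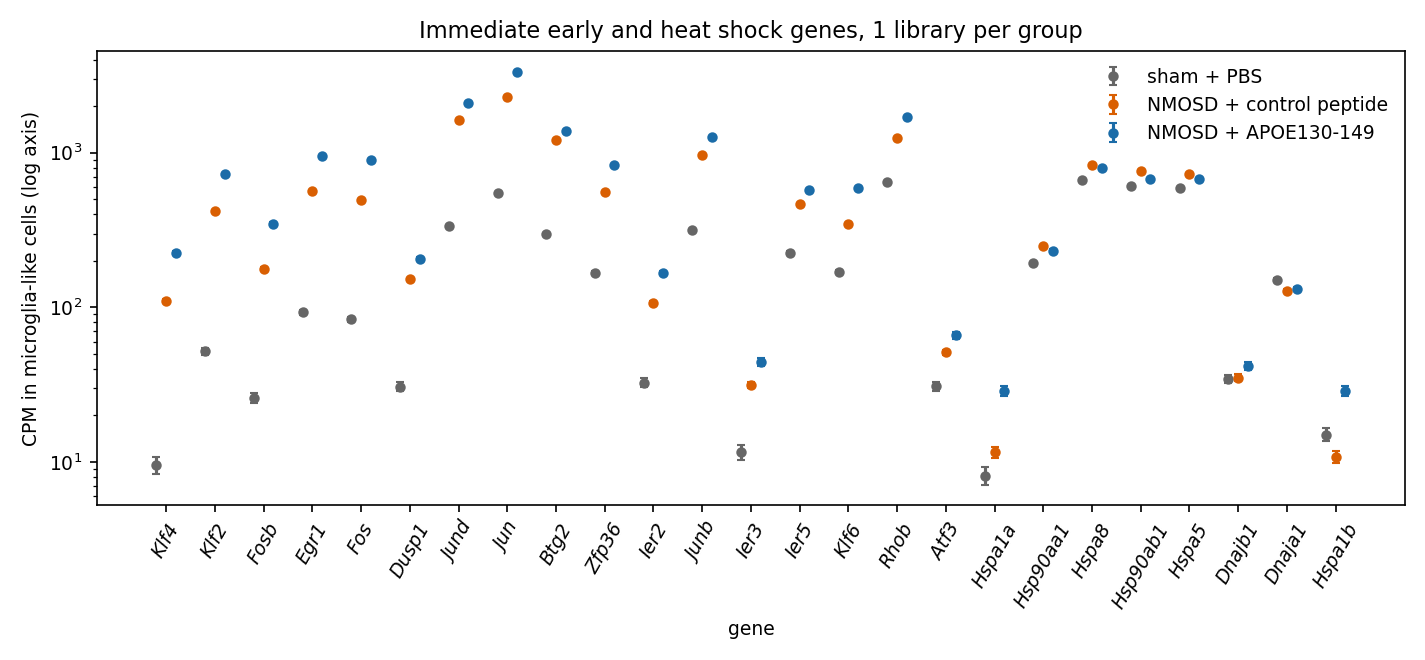
Levels of the measured immediate early and heat shock genes in microglia-like cells: CPM on a log axis (vertical) for each gene (horizontal, ordered by the ratio of NMOSD + control peptide over sham), 1 point per library with its exact 95% Poisson interval. Klf4 lies at 9.51 CPM in sham, 110 CPM with the control peptide and 224 CPM with APOE130-149.

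The rule for named genes took 12 genes in each direction. The other higher ones were Klf2 (8.11-fold), Fosb (6.88-fold), Ppp1r15a (5.58-fold), Rgs1 (4.98-fold), Dusp1 (4.95-fold), Hist1h3d (4.89-fold), Jund (4.88-fold) and Jun (4.17-fold), besides Ttr. Ppp1r15a is a stress-induced regulator of translation, Rgs1 a regulator of G protein signalling and Dusp1 a phosphatase of MAP kinases. The differences in the other direction were smaller. The acute phase gene Saa3 was 2.00-fold lower [1.90 to 2.11] in the NMOSD library, with 108 CPM in sham and 53.8 CPM in NMOSD, and 0.25% of the cells held 29.1% and 31.3% of its UMIs. Rsrp1 (1.87-fold lower), Tardbp (1.68-fold), Luc7l3 (1.62-fold) and Fubp1 (1.55-fold) were among the lower ones. Gfm2 (1.66-fold), Zfp950 (1.61-fold), Fam13b (1.56-fold) and the long noncoding RNA gene Dleu2 (1.79-fold) were also lower. Ccdc152 (2.07-fold lower), Tsix (1.82-fold) and Adap2os (1.53-fold) overlap Selenop, Xist and Adap2, and use of strand in the counting is not stated, so their reads cannot be told from those of the overlapping genes. The same doubt holds for Gfm2 (overlapping Nsa2), Dleu2 (Trim13 and Kcnrg), Tardbp (Masp2), Zfp950 (Grk5), Fam13b (Pkd2l2), Ppp1r15a (Tulp2), Dusp1 (Ergic1) and Jun (Junos), and Hist1h3d belongs to a family of histone genes of like sequence.

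Markers of other cell types went with the same comparison. Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321), the choroid plexus gene for transthyretin, was at 0.712 CPM in sham microglia-like cells and at 96.3 CPM in the NMOSD + control peptide library, 135-fold higher [87.4 to 221]; over all cells, whatever their class, its log2 ratio was 6.29. The haemoglobin gene Hbb-bs stood at 0.214 and 82.7 CPM, the monocyte gene Fn1 at 2.78 and 33.4 CPM, and the neutrophil gene S100a9 at 136 and 219 CPM. Other markers of these types did not rise alike. The monocyte gene Lyz2 stood at 747 and 802 CPM, and the neutrophil gene Csf3r was lower in NMOSD, at 316 and 268 CPM. These levels stand beside every gene group given for this comparison. The dendritic cell gene Mycl was at 13.1 and 9.89 CPM, the T cell gene Lat at 0.819 and 0.660 CPM, the B cell gene Ighm at 248 and 237 CPM, the astrocyte gene Slc1a3 at 189 and 180 CPM and the oligodendrocyte gene Cnp at 38.5 and 39.4 CPM. The immunoglobulin gene Igkc was higher in sham, at 21.2 CPM against 0.532 CPM, and at 0.203 CPM with APOE130-149. An unnamed cluster with 31628 CPM of Igkc in sham held 73 sham cells, 3 with the control peptide and 2 with APOE130-149. The oligodendrocyte precursor and mural cell gene Cspg4 stood at 1.10 and 5.45 CPM, the neuronal gene Celf4 at 2.99 and 1.94 CPM, the endothelial gene Ly6a at 23.9 and 23.2 CPM, the mast cell gene Cma1 at 1.10 and 3.55 CPM, and the natural killer cell gene Ccl5 at 105 and 71.7 CPM. The border-associated macrophage gene Mrc1 stood at 15.3 and 17.7 CPM.

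Genes tied to microglial states differed less than the immediate early genes. Of 22 measured genes of the disease-associated microglia list, a program of lipid handling and phagocytosis, 4 were at least 1.5-fold higher in NMOSD + control peptide and 18 were neither (median log2 ratio 0.21, percentile 100). The 4 were Igf1 (4.20 CPM in sham and 12.1 CPM in NMOSD), Spp1 (23.1 and 59.6 CPM), Fabp5 (8.15 and 19.8 CPM) and Lpl (67.1 and 131 CPM). For Spp1, 61.0% of the sham UMIs and 49.8% of the NMOSD UMIs came from 0.25% of the microglia-like cells. Of 21 proliferation genes, 8 were at least 1.5-fold higher and 13 were neither (median log2 ratio 0.48, percentile 100), among them Ube2c (14.7 and 28.2 CPM), Birc5 (12.6 and 22.9 CPM) and Mki67 (34.9 and 54.7 CPM, with 45.4% and 24.97% of UMIs in 0.25% of cells). The homeostatic microglia list held 18 measured genes, of which 1, the AP-1 gene Jun that also stands in the immediate early list, was at least 1.5-fold higher and 17 were neither (median log2 ratio -0.05, percentile 10.6). P2ry12, a purine receptor of homeostatic microglia, stood at 2627 CPM in sham and 2422 CPM in NMOSD, and Tmem119 at 1148 and 1187 CPM. That median turned positive under median-of-ratios scaling, TMM scaling and a limit on UMIs per cell.

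Antigen presentation and inflammatory genes gave small medians in this comparison. Of 9 MHC class II genes, 0 were at least 1.5-fold apart, with a median log2 ratio of -0.25 (percentile 0.885); H2-Eb1 stood at 55.5 CPM in sham and 38.4 CPM in NMOSD, and H2-Ab1 at 114 and 79.9 CPM. Over all cells, whatever their class, that median was 0.10. None of the 19 MHC class I genes was at least 1.5-fold apart (median -0.04, percentile 53.0). The 28 type I interferon response genes likewise held 0 that were at least 1.5-fold apart, and their median log2 ratio of 0.05 (percentile 99.2) changed sign with 4 of the alternative settings, down to -0.08, so it has no direction here. Of 24 inflammatory cytokine and NF-kB genes, 2 were higher, Tnf (4.10 and 10.4 CPM, with 32.2% and 21.2% of UMIs in 0.25% of cells) and Ccrl2 (17.8 and 33.8 CPM), 1 was lower, Saa3, and 21 were neither (median 0.0033, percentile 92.6). Among 12 chemokine genes, Ccl4 (94.1 and 189 CPM), Pf4 (5.91 and 11.3 CPM) and Ccl3 (92.8 and 175 CPM) were higher and 9 were neither (median 0.04, percentile 89.3). The alternative activation list held 11 measured genes, of which 3 were higher: Socs3, an inhibitor of cytokine signalling (37.0 and 94.5 CPM), Ccl24 (6.73 and 10.7 CPM) and Arg1 (0.285 and 13.2 CPM; median 0.05, percentile 91.3). Without the 0.25% of cells with most of its UMIs, Ccl24 stood at 6.01 and 8.43 CPM, less than 1.5-fold apart. For Arg1, 92.1% of the UMIs of the NMOSD library came from 0.25% of its cells.

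In the metabolic and signalling lists few members were 1.5-fold apart. Plin2, a coat protein of lipid droplets (39.1 CPM in sham and 60.7 CPM in NMOSD), and Apoc1 (13.7 and 20.6 CPM) were higher and Ch25h (28.6 and 17.1 CPM) lower among 15 cholesterol efflux genes, with 12 neither (median -0.07, percentile 44.4). The Ch25h difference rested on few cells: 0.25% of sham cells held 49.8% of its UMIs, and without such cells its levels were 14.8 and 12.8 CPM. The mitochondrially encoded list of 13 genes held 1 higher, mt-Nd1 (1502 and 2352 CPM), and 2 lower, mt-Atp8 (60.1 and 30.8 CPM) and mt-Nd6 (23.6 and 13.5 CPM), with a median of 0.13 (percentile 97.0). None was 1.5-fold apart among 92 nuclear genes of oxidative phosphorylation (median 0.12, percentile 100), 20 oxidative stress genes (0.12, percentile 99.9), 88 ribosomal protein genes (0.07, percentile 95.4), 26 lysosome and phagocytosis genes (0.09, percentile 94.5) and 16 glycolysis genes (0.07, percentile 96.4). The same held for 12 complement genes (-0.11, percentile 14.4), 13 Fc gamma receptor and signalling genes (-0.02, percentile 45.3), 9 cholesterol synthesis genes (0.04, percentile 93.8), 6 apolipoprotein E receptor genes (-0.11, percentile 26.4) and 14 TGF-beta signalling genes (-0.07, percentile 33.4). In all, 7 of the 22 lists stood apart from random lists, lying outside the middle 95% of them. The medians of 12 of the 22 lists changed sign under at least 1 alternative setting and have no direction here: the homeostatic, interferon, MHC class I, MHC class II, inflammatory, chemokine (from -0.12 to 0.31), complement, Fc gamma receptor, cholesterol efflux, cholesterol synthesis, alternative activation and TGF-beta lists. The median log2 ratio over 3497 genes at 50 CPM or more was -0.07, with 90% of them between -0.39 and 0.28.

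The second comparison, NMOSD + APOE130-149 against NMOSD + control peptide, asks what the apolipoprotein E peptide adds after induction. Immediate early genes were higher here too, in the APOE130-149 library, part of them by at least 1.5-fold: 9 of 25 members of the list were at least 1.5-fold higher, 0 lower and 16 neither (median log2 ratio 0.44, percentile 100). The 9 were 7 of the 17 immediate early genes that were higher in the first comparison and a pair of heat shock genes. The other 10 of the 17 were less than 1.5-fold apart, down to Btg2 at 1.14-fold, and the ratio intervals of all 17 lay above 1. Klf4 was 2.03-fold higher [1.95 to 2.11], at 110 CPM with the control peptide and 224 CPM with APOE130-149, Fos 1.81-fold higher [1.77 to 1.84] and Egr1 1.69-fold higher [1.66 to 1.72]. Adamts1 (ENSMUSG00000022893, chromosome 16, 85793827 to 85803113), a secreted protease, had the highest ratio among named genes at 50 CPM or more, 2.27-fold [2.13 to 2.41], at 41.0 against 92.9 CPM. The chemokine gene Ccl3 was 1.75-fold higher [1.70 to 1.81] and Socs3 1.64-fold higher [1.57 to 1.72]. The heat shock pair, below 50 CPM, was Hspa1a (11.6 and 28.8 CPM) and Hspa1b (10.8 and 28.8 CPM).

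The remaining named genes with higher levels were Fosb (1.96-fold), Klf2 (1.73-fold), Klf6 (1.70-fold), Ccdc152 (1.61-fold), Tsc22d3 (1.58-fold), a glucocorticoid-induced gene, and Ier2 (1.55-fold). In the other direction no ratio of a named gene at 50 CPM or more reached 1.5-fold. Cxcl10, an interferon-induced chemokine, was 1.47-fold lower [1.37 to 1.58], with 62.7 CPM under the control peptide and 42.5 CPM under APOE130-149, but over all cells, whatever their class, it was higher (log2 ratio 0.09), and 0.25% of microglia-like cells held 38.2% and 21.3% of its UMIs. Its span overlaps that of Art3, and that of Akap9 overlaps Cyp51. S100a8, a neutrophil gene, was 1.33-fold lower [1.28 to 1.39], and this turned without the 0.25% of cells with most of its UMIs, which held 51.0% of them in the control peptide library (log2 ratio 0.09). The MHC class I genes H2-Q6 (1.32-fold lower) and H2-Q7 (1.23-fold lower) are close paralogs and can share reads. Ttr was 1.38-fold lower, with a log2 ratio of -1.18 over all cells, and Atrx (1.32-fold), Ddx46 (1.29-fold), Pnn (1.27-fold), Akap9 (1.25-fold), Eif3i (1.25-fold), Anp32b (1.24-fold) and Bod1l (1.24-fold) were also lower. Anp32b was level with cells thinned to 2000 UMIs (log2 ratio 0.01). Markers of other cells differed here as well: Hbb-bs stood at 82.7 CPM with the control peptide and 15.9 CPM with APOE130-149, Fn1 at 33.4 and 29.8 CPM, and S100a9 at 219 and 194 CPM. Lyz2 and Csf3r went the other way, at 802 and 967 CPM and at 268 and 279 CPM.

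**Figure D3:**
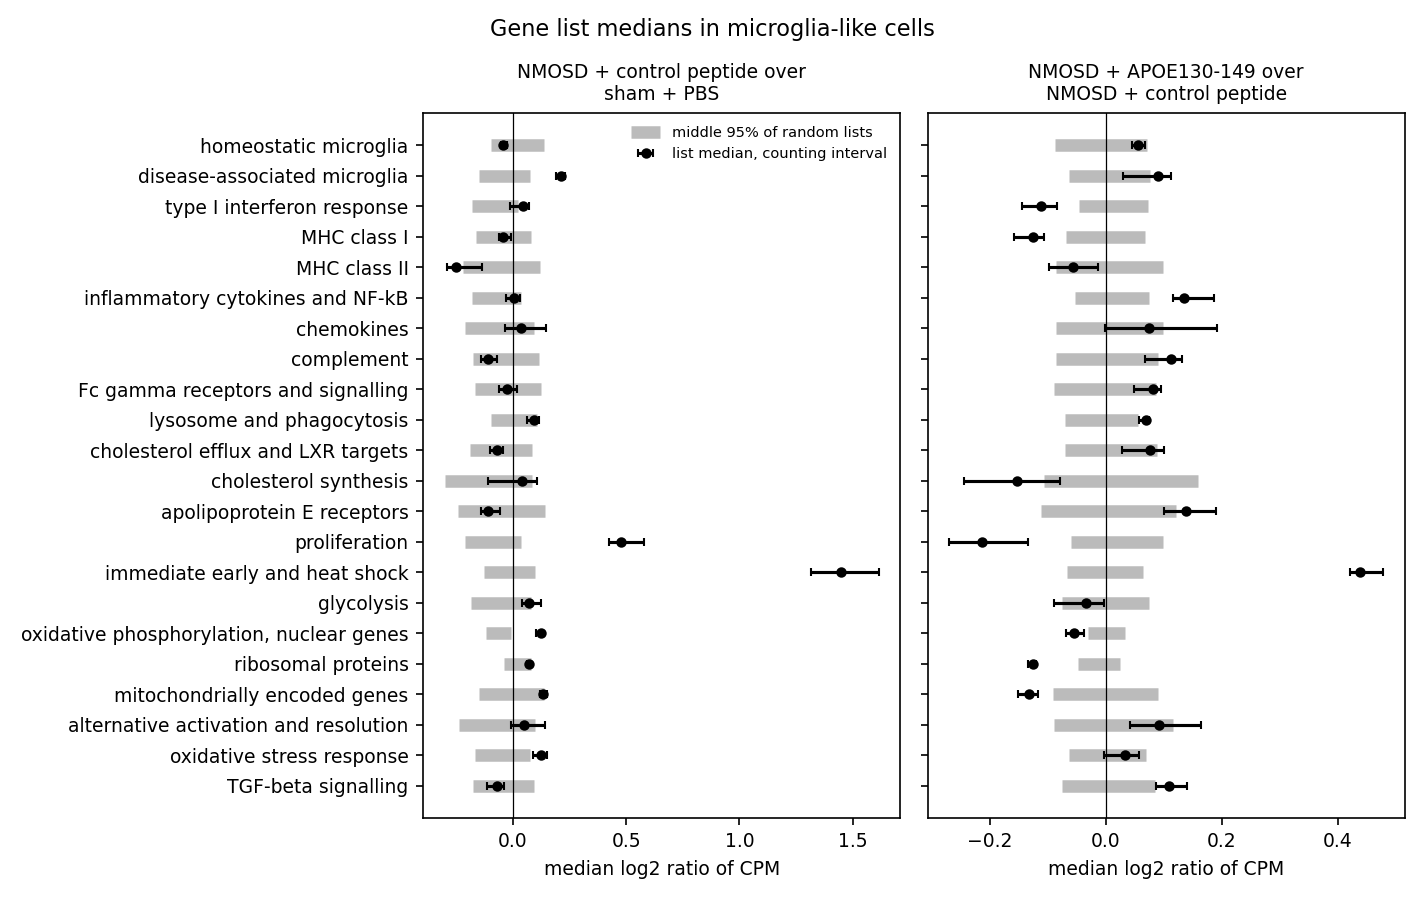
Medians of the 22 gene lists in microglia-like cells: log2 ratio of CPM (horizontal axis, a separate scale in each panel) for each list (vertical axis), with the interval from counting error (bars) and the range of the middle 95% of random lists (grey). The immediate early and heat shock list lies at 1.45 for NMOSD + control peptide over sham and at 0.44 for APOE130-149 over the control peptide.

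Most list medians of this second comparison lay within 0.2 of 0 on the log2 scale, and 14 of the 22 lists stood apart from random lists. Inflammatory cytokine and NF-kB genes had a median of 0.14 (percentile 100) with 0 of 24 members 1.5-fold apart; Tnfaip3, an inhibitor of NF-kB, stood at 38.3 CPM with the control peptide and 56.9 CPM with APOE130-149. Disease-associated microglia genes had a median of 0.09 (percentile 98.9) with 0 of 22 apart, and Csf1 at 41.6 and 54.4 CPM. The homeostatic list had a median of 0.05 (percentile 94.5), and P2ry12 stood at 2422 and 2621 CPM. Type I interferon response genes had a median of -0.11 (percentile 0), with 1 of 29 lower, Rsad2 (18.0 and 11.9 CPM, with 26.7% and 24.3% of UMIs in 0.25% of cells, and 13.7 and 9.25 CPM without them, less than 1.5-fold apart). MHC class I genes had a median of -0.13 (percentile 0.02) and MHC class II genes of -0.06 (percentile 10.8), with 0 of 19 and 0 of 9 apart. Proliferation genes had a median of -0.21 (percentile 0) with 0 of 21 apart, and Cenpe at 17.7 and 11.9 CPM; with each cell given equal weight that median was 0.01. Among 13 chemokine genes Ccl3 was higher and Cxcl9 (19.4 and 5.29 CPM) lower (median 0.07, percentile 93.3). For Cxcl9, 82.2% of the UMIs of the control peptide library came from 0.25% of its cells. The alternative activation list had 1 of 11 higher, Socs3, and 1 lower, Arg1 (13.2 and 1.30 CPM), with the few Arg1 cells given above (median 0.09, percentile 93.6).

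The lists on lipids and apolipoprotein E receptors held no gene that was 1.5-fold apart between the 2 NMOSD libraries. Cholesterol synthesis genes had a median of -0.15 (percentile 0.43, 8 genes, Cyp51 at 10.9 and 8.05 CPM), cholesterol efflux genes of 0.08 (percentile 95.5, 16 genes) and apolipoprotein E receptor genes of 0.14 (percentile 98.7, 6 genes, Lrp5 at 42.4 and 51.9 CPM). Cyp51 overlaps Akap9, which stood at 166 and 133 CPM, and with use of strand not stated their reads cannot be told apart. Complement genes had a median of 0.11 (percentile 99.3), with C3 at 12.1 and 16.0 CPM, TGF-beta signalling genes of 0.11 (percentile 99.4), lysosome and phagocytosis genes of 0.07 (percentile 99.0), Fc gamma receptor and signalling genes of 0.08 (percentile 96.8), oxidative stress genes of 0.03 (percentile 80.8) and glycolysis genes of -0.03 (percentile 19.6). The oxidative stress, glycolysis and proliferation medians changed sign under at least 1 alternative setting. Ribosomal protein genes had a median of -0.13 (percentile 0) and nuclear genes of oxidative phosphorylation of -0.05 (percentile 0.01). Of 13 mitochondrially encoded genes, mt-Atp8 (30.8 and 19.5 CPM) and mt-Nd5 (283 and 186 CPM) were lower (median -0.13, percentile 0.155). Over 3362 genes at 50 CPM or more the median log2 ratio was -0.0014, with 90% between -0.18 and 0.23.

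Set against sham, the APOE130-149 library had 19 of 25 immediate early and heat shock genes at least 1.5-fold higher and 0 lower (median log2 ratio 1.94), 6 of 22 disease-associated microglia genes higher (median 0.30), which were Spp1, Igf1, Fabp5, Lpl, Csf1 and the knocked-out gene Apoe, and 4 of 13 chemokine genes higher with 3 lower (median 0.35). The 3 included Cxcl10, which without the 0.25% of cells with most of its UMIs, 62.3% of them in sham, stood at 31.2 CPM in sham and 34.5 CPM with APOE130-149. Of 9 MHC class II genes 2 were lower, H2-Ab1 and H2-Eb1 (median -0.14), and of 13 mitochondrially encoded genes 4 (median -0.03). The log2 ratios of both main comparisons were negatively related across 8558 genes (Pearson's r = -0.300, covariance -0.0180), genes not being independent replicates. Both comparisons use the control peptide library, with opposite signs, and simulated libraries without any difference gave a mean r of -0.360 and a mean covariance of -0.00158 over 100 draws. The observed covariance minus the simulated one was -0.0164. With the UMIs of the control peptide library divided at random between both comparisons, r was -0.263 and the covariance -0.0164, which leaves any effect of that 1 library in place. Of the 17 immediate early genes at least 1.5-fold higher in the first comparison, 7 were so in the second as well, and all 17 had ratio intervals above 1 there, against the direction of this relation.

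Shares of microglia-like cells with at least 1 UMI were compared after thinning each cell to 2000 UMIs, which left out 8, 21 and 7 cells of the sham, control peptide and APOE130-149 libraries. Klf4 was found in 1.22% [0.854 to 1.70] of sham cells, 14.99% [13.9 to 16.1] with the control peptide and 26.9% [24.7 to 29.1] with APOE130-149; without thinning the shares were 4.71%, 37.5% and 54.9%. In neutrophil-like cells the thinned Klf4 shares were 1.92% [0.0487 to 10.3], 14.2% [8.62 to 21.5] and 14.9% [7.66 to 25.04]. Neutrophil-like cells carried RNA of microglia, as the P2ry12 levels above show, so their shares set no clean background, and no order was read from shares of cells. Median depths before thinning were 8361, 8002 and 10523 UMIs in microglia-like and 11372, 15562 and 15198 UMIs in neutrophil-like cells. Spp1 was found in 1.15%, 2.93% and 3.52% of thinned microglia-like cells, 1.92%, 4.72% and 2.70% of neutrophil-like cells, and 4.25%, 8.61% and 12.4% of microglia-like cells without thinning. Mki67 was found in 1.68%, 2.96% and 3.01% of thinned microglia-like cells, 3.85%, 2.36% and 2.70% of neutrophil-like cells, and 3.31%, 5.79% and 7.13% without thinning. For Cxcl10 the shares were 1.85%, 3.01% and 3.58% in thinned microglia-like cells, 1.92%, 2.36% and 5.41% in neutrophil-like cells, and 5.37%, 8.02% and 10.5% without thinning.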

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

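No test was run on this result. An unnamed cluster of cells with few UMIs, outside the microglia-like class and so in its sums only under the settings with all cells or with low-UMI clusters included, made up a larger share of both NMOSD libraries than of sham. Cluster 9 held 4.79% [4.21 to 5.42] of cells with the control peptide and 7.31% [6.21 to 8.53] with APOE130-149, against 2.01% [1.61 to 2.48] in sham. Its cells had medians of 1633 UMIs in sham, 1366 with the control peptide and 1318 with APOE130-149. The nuclear long RNA Malat1 stood at 43427, 44076 and 40892 CPM in them, against 24709, 21438 and 20133 CPM in microglia-like cells. The microglial gene P2ry12 was about as high in them as in that class, at 2656, 2612 and 2697 CPM against 2627, 2422 and 2621 CPM. Its share depends on the clustering and on the sort, and has no replicate check.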

How the results depend on the processing

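Settings on removal by doublet score, the UMI limit per cell, inclusion of low-UMI clusters, unnamed clusters left out of the total, top cells left out, and the relation without the immediate early list were chosen after seeing the data. No paired analysis was possible because each group is 1 library and all share replicate number 1. The cause of the shifts below was not tested. Of 746 alternative list medians, 553 stayed within the counting interval, 187 moved beyond it and 6, of lists that stood apart from random lists, reversed. For named genes 569 of 720 stayed, 147 moved and 4 reversed, for microglia-like shares 10 of 27 stayed and 17 moved, for shares of the smaller classes 100 of 132 stayed and 32 moved, and for shares of cells with a UMI 2 of 24 stayed and 22 moved.

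Microglia-like shares in sham, control peptide and APOE130-149 were 58.6%, 71.7% and 66.4% without a filter on cells, 86.4%, 83.1% and 79.7% with the stricter filter, 58.6%, 73.1% and 69.2% at resolution 2, 93.4%, 88.8% and 86.3% with low-UMI clusters included, and 93.5%, 88.3% and 85.4% with unnamed clusters left out of the total. Removal by doublet score gave 66.2% in sham, and the UMI limit 83.1% with the control peptide.

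Shares of the smaller classes follow in the same order of libraries. Border-associated macrophage-like cells were 0.733%, 2.35% and 2.57% at resolution 2, 1.11%, 1.97% and 3.002% with the UMI limit, and 2.28% in sham with unnamed clusters left out. Neutrophil-like cells were 3.19%, 3.69% and 5.20% without a filter on cells, 0.740%, 1.496% and 2.25% with the UMI limit, 2.77% in sham and 3.15% with the control peptide at resolution 2, 2.94% and 3.33% with removal by doublet score, and 1.86% in sham with unnamed clusters left out. Monocyte-like cells were 2.46%, 5.77% and 6.57% at resolution 0.5, and 1.48% in sham with the UMI limit. Choroid plexus cell-like cells were 0%, 0.204% and 0.168% with the stricter filter, 0.024%, 1.14% and 0.395% at resolution 2, 0%, 1.15% and 0.420% with removal by doublet score, and 0.021% in sham without a filter. No cluster was called border-associated macrophage-like at resolution 0.5, endothelial cell-like without a filter on cells, or endothelial or choroid plexus cell-like with the UMI limit, so these settings gave no value.

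For control peptide over sham, the homeostatic median log2 ratio was -0.026 without a filter on cells, -0.062 at resolution 2, 0.033 with median-of-ratios, 0.049 with TMM, -0.0057 with equal weight per cell, -0.016 thinned, 0.013 with the UMI limit and -0.013 with low-UMI clusters. The disease-associated median was 0.15 without a filter on cells, 0.14 over all cells, 0.29 with median-of-ratios, 0.31 with TMM, 0.18 with the UMI limit and 0.19 with low-UMI clusters. The interferon median was 0.076 without a filter, 0.089 with the stricter filter, 0.12 with median-of-ratios, 0.14 with TMM and 0.073 with top cells left out, and reversed to -0.033 with equal weight per cell, -0.037 thinned, -0.014 with removal by doublet score and -0.076 with the UMI limit. The inflammatory median was 0.082 with median-of-ratios, 0.099 with TMM and 0.061 thinned. Over all cells the MHC class II median reversed to 0.10 and Ttr was at 6.29. Of the 22 list medians, 12 took the other sign under at least 1 setting, such as chemokines (-0.12 to 0.31) and alternative activation (-0.046 to 0.27).

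For APOE130-149 over control peptide, the homeostatic median was 0.036 with median-of-ratios, 0.023 with TMM and 0.039 with a total without mitochondrial and ribosomal genes. The disease-associated median was 0.14 without a filter on cells and 0.12 with the stricter one. The interferon median was -0.18 without a filter, -0.18 with the stricter filter, -0.16 at resolution 2, -0.059 thinned and -0.19 with the UMI limit. The inflammatory median was 0.10 with TMM, 0.097 with removal by doublet score and 0.079 with the UMI limit. The proliferation median reversed to 0.011 with equal weight per cell. Cxcl10 reversed to 0.085 over all cells, S100a8 to 0.14 over all cells and to 0.086 with top cells left out, and Anp32b to 0.0084 thinned. Ttr was at -1.18 over all cells and Bod1l at -0.57 thinned. Here 3 of the 22 list medians took the other sign: glycolysis, oxidative stress and proliferation. The correlation of both main comparisons was -0.223 at 50 CPM or more and -0.363 without the immediate early list. At this depth, levels in microglia-like cells under 0.107 CPM in sham, 0.0638 CPM with the control peptide and 0.122 CPM with APOE130-149 could not be told from 0.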

Other observations

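The tests on immediate early genes, on Ttr and on splicing factor genes as a class were chosen after the results were seen. Those on nuclear RNA and on gene length were chosen before their own values were seen, but on lists added after the data were seen. Monocyte-like cells differed in genes of proliferation. Their list median (27 genes) was 0.93 [0.72 to 1.24] on the log2 scale for NMOSD + control peptide over sham, and -2.85 [-3.01 to -2.26] for APOE130-149 over the control peptide. Mki67 UMIs were found in 5 of 35 monocyte-like cells in sham, 13 of 60 with the control peptide and 1 of 38 with APOE130-149, with 51, 208 and 8 UMIs, and Top2a stood at 39.1, 183 and 9.75 CPM. So few cells decide these levels that 1 cell held 51.0% of the sham Mki67 UMIs.

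Border-associated macrophage-like cells had an MHC class II median log2 ratio of -0.50 [-0.73 to -0.28] for the control peptide over sham and -0.20 [-0.27 to -0.12] for APOE130-149 over the control peptide, with Cd74 at 8297, 3780 and 3227 CPM and H2-Aa at 3756, 1652 and 1365 CPM in sham, control peptide and APOE130-149. Among markers of the class itself, Mrc1 stood at 801, 393 and 542 CPM and Pf4 at 489, 258 and 458 CPM, while Ccl8 stood at 248, 239 and 265 CPM. The homeostatic microglia list had a median of 0.47 in the same cells for the control peptide over sham, and P2ry12 stood at 1429, 1942 and 2021 CPM. With markers of the class this far apart, no difference in MHC class II genes is read from these values.

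Immediate early genes had a list median of 1.45 in microglia-like cells of NMOSD + control peptide over sham. With each cell thinned to 2000 UMIs the median was 1.35. CPM are already scaled to all UMIs, so this does not decide whether more UMIs per cell are the cause. Microglia-like cells had medians of 8347 UMIs in sham and 7977 with the control peptide. Handling that acts alike on every cell type cannot be told apart from the other explanations. The list median was 0.73 in neutrophil-like and 0.48 in monocyte-like cells, on both sides of the bound set. It was 1.13 [0.92 to 1.31] in border-associated macrophage-like cells, over 27 members whose median in microglia-like cells was 1.06. All these classes carried microglial RNA. Single members also went apart, in both directions. In neutrophil-like cells the ratio of Fos was 0.822 [0.738 to 0.917], but that of Klf4 9.04 [4.34 to 22.7], Jun 5.45 [4.69 to 6.35] and Egr1 2.74 [2.25 to 3.36]. In monocyte-like cells Klf4 was at 0.953 [0.771 to 1.18], Fos at 1.44 [1.19 to 1.74], Jun at 2.74 [2.26 to 3.35] and Egr1 at 2.66 [1.64 to 4.53]. Microglia-like cells had 5.94 for Fos, 11.6 for Klf4, 4.17 for Jun and 6.10 for Egr1. With 1 library per group, handling or a library batch acting on microglia may also be the cause and cannot be told apart from the groups. Neither can be told apart from NMOSD induction or from control peptide against PBS. Both of these differences are named by the design and stay open and untested.

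Ttr was 135-fold higher in microglia-like cells of the control peptide library than in sham. Free RNA from choroid plexus cells is a candidate explanation that the values go with: in that library Ttr stood at 96.3 CPM in microglia-like, 73.2 CPM in border-associated macrophage-like, 73.2 CPM in neutrophil-like and 57.9 CPM in monocyte-like cells, at most 1.66 times apart. The CD45int CD11b+ sort should remove such cells, though a class like them was found, and Enpp2, another of their genes, stood at 3.57 CPM in microglia-like cells against 0.071 CPM in sham. No biological explanation was tested.

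Splicing factor genes (26 genes, of which 8 had been seen to be low before the list was written) had a median log2 ratio of -0.24 [-0.28 to -0.22] for the control peptide over sham. Subtracting genes of like length left that median at -0.20 [-0.21 to -0.17]. Counts of intronic reads in long genes are not excluded by this, since the 8 members already seen to be low stay in the median. A lower share of nuclear RNA cannot be told apart from other causes: nuclear-retained long RNAs had a median of -0.14 [-0.18 to -0.10], with Malat1 at -0.20 but Neat1 at 0.84, and after subtracting genes of like length 0.04 [-0.0015 to 0.07], where a loss of nuclear RNA from long genes would be subtracted too. In the control peptide library a shift of the class cannot be told apart from low levels of the 8 genes already seen: the other 18 members had a median of -0.074 [-0.10 to -0.06] against -0.084 for all genes, which leaves out the members chosen for being low and so excludes nothing. In the APOE130-149 library those 18 had a median over sham of -0.25 [-0.27 to -0.22] against -0.06 for all genes (percentile 0 among random lists), so the 8 genes are argued against as the whole cause there, while a shift of the class stays open, its interval reaching the bound set.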
